A study of Homo sapiens with 4 samples.

How the data were processed

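Total RNA from 2 human ocular melanoma cell lines, OCM1 and OCM1a, each with and without decoyed CTCF, was extracted with Trizol, labelled with biotin and hybridised to single-colour Affymetrix arrays, per the labels' protocols. There were 4 arrays, 1 for each line and condition, and each sample was placed in its group by its title. Nothing in the labels gives a culture, passage, slide or scan date, so no batch could be tested. An entry for developmental state in the labels describes early embryos and was not used.

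The deposited values were log2 signals per probe set. The log2 scale was taken from the values, which ran from 2.84 to 14.8, a range that a 16-bit scanner allows for log2 and not for log10 or the natural log. MAS5 was named in the submitters' processing notes with no version or role. The background correction, summarization and normalization are not given in the sources used here. The 4 arrays had nearly equal quantiles, with medians of 7.13, 7.16, 7.12 and 7.14, so a normalization between arrays had already been applied, and none was added. The offset that had been planned for a linear table was therefore not needed.

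The table held 49395 probe sets, of which 102 were Affymetrix controls. The platform annotation gave 1 gene symbol for 44994 probe sets and several for 1832, and 2473 others were not listed. Symbols were updated through Entrez identifiers against the RefSeq gene table of assembly GRCh38.p14, which matched 44967 of the 44994, and 3 list symbols were brought up to date. That table served only for names, for the chromosome of a gene and for the order of neighbouring genes. A gene took the value of its probe set with the highest mean over the 4 arrays, which gave 18107 genes. The upper 50% of genes by mean signal, 9054 genes with a mean log2 signal of at least 7.67, were tested. The number of arrays limits the precision.

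Choices of test, filter, gene lists and alternatives were made before the data were examined. The decoy effect over both lines and the difference between lines came from 1 limma model with an additive term for each (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). This left 1 residual degree of freedom per gene, and the empirical Bayes prior had 6.40 degrees of freedom and an SD of 0.158. The lines are the replication of the decoy, and arrays were paired by line because both arrays of a pair come from the same cell line. Within a line there was 1 array per condition, so differences there were counted at 2-fold or more with no test. The residual of this model is the disagreement of the decoy difference between the lines. The p-values measure that spread, which may be technical in part and may hold a real line-specific response. The names of 27 gene lists were fixed, of which 21 had at least 3 tested members. They were compared with 10000 random lists of the same size drawn from 10 bins of mean expression, and tested over both lines with camera at a preset correlation of 0.01. An alternative estimated the correlation from the data, with 1 residual degree of freedom per gene. That is too little to decide a call, and the preset value is an assumption. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

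Genes were named by a rule. It took NTS and CTCF, each measured gene of the neurotensin signalling and NTS neighbour lists, up to 10 genes higher and 10 lower among those at least 2-fold the same way in both lines, the 5 largest increases and decreases in each line, the 8 genes highest in either line, and up to 4 members of each list with the largest mean difference. Withheld names and sex-linked genes were left out by the rule. Genes named outside it were chosen after their values were seen, and the text says so.

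The limma step was tested on 20 simulated data sets of the decoy effect over both lines, each with 9054 genes and 200 changed genes and with no difference in effect between the lines. It recovered 85.8% of 2-fold and 99.9% of 4-fold changes, with 20.5 false calls on average. The step with random lists, tested on simulated shifts of the OCM1 difference over 9054 genes, placed 97.5% of 40 lists of 15 genes shifted by 0.3 above the 97.5th percentile, and put 10.0% of unshifted lists outside the central 95%. Alternatives covered quantile normalization and median centring of the arrays, the filter on dim genes, the probe sets of a gene, the variance model, the block for cell line, the thresholds and the camera correlation. Alternatives on the control array, on chromosomes, on signals under background and, for lists, on a stricter filter and centring were added after seeing the data.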

Results

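Expression was measured in OCM1 and OCM1a, cell lines grown from human ocular melanoma, with and without decoyed CTCF. CTCF is a zinc-finger protein that binds insulator sites and anchors chromatin loops, and the series title places the study at the locus of NTS, the gene of the neuropeptide neurotensin. How the decoy was made, and what the cells without it received, is not given in the sources used here. Each of the 4 groups held 1 array, so no value within a line has a replicate error. The arrays without decoy were the most alike, with a Pearson correlation of 0.997 across probe sets and an SD of the log2 difference of 0.197. The SD was 0.268 between the OCM1 arrays, 0.324 between the OCM1a arrays and 0.373 between the arrays with decoy. Control transcripts also differed. Poly-A spike-ins had a median difference with decoy of -0.58 in OCM1 and 0.56 in OCM1a, and 18S rRNA of 0.13 and 1.13. The OCM1a array without decoy stood apart in both, at -1.28 and -1.36 against the OCM1 array without decoy. Values below are log2 differences, decoy minus no decoy, with OCM1 first, unless stated otherwise.

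The first question was whether NTS, the locus in the series title, had a different level with decoyed CTCF. The NTS probe set read lower with decoy in both lines, at a signal not shown to be above background. Its log2 signal was 7.31 without and 6.02 with decoy in OCM1, and 5.86 and 4.92 in OCM1a. Background probe sets rich in G and C had medians of 6.71 and 6.89 on the OCM1 arrays without and with decoy, and 6.84 and 6.77 on those of OCM1a. NTS was under them on 3 of the 4 arrays, all but OCM1 without decoy. Background probe sets with fewer G and C had a median of 3.15 on that array, and which background applies to the NTS probes is not given. Against the G- and C-rich background, a floor chosen after seeing the data, NTS was at least 1.33-fold lower in OCM1, and no fold can be given in OCM1a. That bound rests on 1 array, OCM1 without decoy. The arrays without decoy read -1.45 apart for NTS, OCM1a minus OCM1, which is more than the difference with decoy in either line. A further NTS probe set read -0.78 and -0.77, but was under the G- and C-rich background on all 4 arrays. The mean signal of NTS lay at the 27.1 percentile of all genes and under the filter. In limma without that filter its adjusted p was 0.403. Of 18107 measured genes, 3 had decreases at least as large as those of NTS in both lines, NTS included. Among 2601 genes within 0.5 log2 of its mean signal that count was 1, NTS itself. This ranks the readings, and does not show a signal above background. The CTCF transcript, which carries no information on binding of the protein, differed by -0.35 in OCM1 and 0.04 in OCM1a. The neurotensin receptors were also under the filter, with -0.11 and -0.19 for NTSR1 and -0.31 and -0.14 for NTSR2, which was under the G- and C-rich background on all 4 arrays.

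RASSF9 and MGAT4C, the genes directly next to NTS, were too dim to compare with it, while 6 genes of the neighbour list passed the filter that NTS did not. In the RefSeq gene order, RASSF9 lies next to NTS on one side, with 0.11 and -0.04, and MGAT4C on the other, with -0.29 and 0.14. ALX1, a homeobox gene, had -0.22 and -0.21, and TSPAN19 -0.33 and -0.54 at a very dim signal. LRRIQ1 had 0.08 and -0.03, SLC6A15 0.02 and -0.13, and C12orf50 0.04 and -0.38. Of these, RASSF9, MGAT4C, TSPAN19, LRRIQ1 and C12orf50 were under the G- and C-rich background on all 4 arrays. On the far side, KITLG, which encodes the ligand of the KIT receptor, had -0.69 and -0.01. TMTC3 had -0.57 and 0.19, RLIG1 -0.57 and 0.14, and CEP290 -0.29 and 0.17. Over the 6 tested genes of the neighbour list the median was -0.43 in OCM1, at the 0.05 percentile of random lists, and 0.07 in OCM1a, at the 64.9 percentile. The random lists were not drawn from neighbouring genes. Adjacent genes had a rank correlation of 0.17 in OCM1, so the percentile overstates how unusual this list is. Camera gave the list an adjusted p of 0.0689 over both lines, and 0.921 with an estimated correlation.

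**Figure D1:**
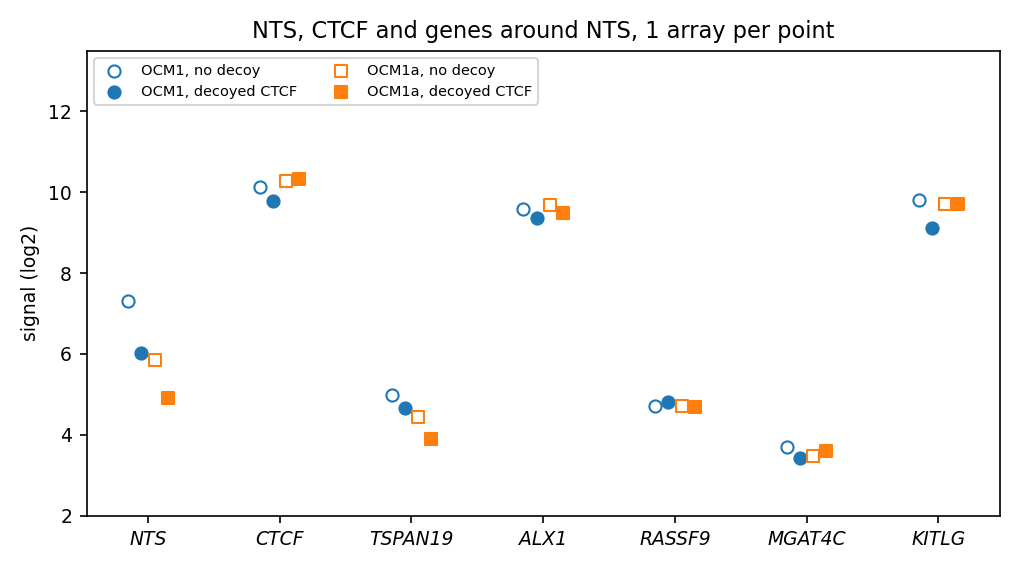
Log2 signal of NTS, CTCF and 5 genes around NTS on each of the 4 arrays, open symbols without and filled symbols with decoyed CTCF, circles for OCM1 and squares for OCM1a. NTS read 7.31 and 6.02 in OCM1 and 5.86 and 4.92 in OCM1a, under the G- and C-rich background on 3 arrays, while CTCF differed by -0.35 and 0.04.

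Across both lines, the genes with the largest shared differences were few. CD70, a ligand of the tumour necrosis factor family, was 2.94-fold and 2.06-fold higher with decoy, and TXNIP, an inhibitor of thioredoxin, 2.15-fold and 2.24-fold higher. PTPRZ1, a receptor-type tyrosine phosphatase, was 2.46-fold and 4.55-fold lower, and MMP8, a collagenase, 2.08-fold and 2.04-fold lower. These 4 genes were those at least 2-fold the same way in both lines, where independent lists would give 0.258 higher and 0.0742 lower. Genes at least 2-fold opposite ways, 8 and 1, also lay above the 0.278 and 0.0689 of independent lists. The excess is thus not particular to a shared direction. In the limma model the mean differences were 1.30 (SE 0.175) for CD70, 1.13 (SE 0.147) for TXNIP, -1.74 (SE 0.220) for PTPRZ1 and -1.04 (SE 0.147) for MMP8, each with an adjusted p of 0.261. No gene passed, 0 higher and 0 lower of 9054, with 447 at an unadjusted p under 0.05 where chance gives 452.7. TXNIP and MMP8, over 2-fold in both lines, were among those not called, so 0 calls do not show that such differences are absent. An intensity trend in the limma variance model called 12 higher and 3 lower, with 524 at an unadjusted p under 0.05, and other settings of limma called 0.

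Tested genes of the interferon response were mostly higher with decoy in both lines. Of 28 listed genes 27 were measured and 11 tested, and 9 of the 11 were higher in both lines. The median was 0.52 in OCM1, above every random list, and 0.24 in OCM1a, at the 99.1 percentile. Over all 27 measured genes it was 0.44, above every random list, and 0.06, at the 98.3 percentile. IFIT1, which binds viral RNA, had 1.61 and 0.95, IFI44 0.52 and 0.83, IFI6 1.18 and 0.26, and the ubiquitin-like ISG15 1.84 and 0.03. Against the OCM1 array without decoy, a control chosen after seeing the data, the OCM1a median was 0.29, at the 99.8 percentile, but IFIT1 had 0.44. Antiviral genes outside the list differed by line. BST2 had 2.33 and -1.65, IFITM1 1.71 and 0.16, and IFITM3, named after its values were seen, 1.06 and 0.83. Camera gave an adjusted p of 5.03e-09, and an adjusted p of 0.745 with an estimated correlation. In limma 0 members passed over all genes and 4 when adjusted over the list alone.

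Several histone transcripts were lower in both lines. The 6 tested of 13 listed genes had medians of -0.71 and -0.64, below every random list in either line, and 5 of the 6 were lower in both. The linker histone H1-2 had -1.03 and -0.70, H2BC12 -0.75 and -1.21, H2AC6 -0.68 and -0.98 and H2BC5 -0.75 and -0.59. These 4 are replication-dependent genes of the histone clusters. H3-3B, a replacement histone named after its values were seen, had 0.01 and 0.06. Camera gave an adjusted p of 3.49e-07, and 0.745 as the adjusted p with an estimated correlation, and 4 members passed limma when adjusted over the list alone against 0 over all genes. With only the upper 25% of genes by signal, an alternative added after seeing the data, the list kept 3 genes and its adjusted p was 0.0845. Histone probe sets can match several near-identical genes. The random lists were matched on mean expression and were not drawn from neighbouring genes, while clustered histone genes lie near each other. Adjacent genes had rank correlations of 0.17 in OCM1 and 0.25 in OCM1a, so the percentiles may overstate how unusual this list is. Parts of several chromosomes were shifted in OCM1a, as given below. Whether the histone decrease goes beyond shifts of neighbouring genes was not tested. Among all 61 measured genes of the clusters, a set formed after seeing the data, the medians were -0.12 and -0.19, and over the 8 tested -0.48 and -0.40. Of these 8, 4 were lower in both lines, and the others, named after their values were seen, were H2AC20 with -0.27 and 0.49, H4C12 with -0.22 and 0.09, H4C3 with 0.15 and -0.21 and H3C8 with 0.01 and -0.18. The linker histone H1-10, also named after its values were seen, was higher, with 0.61 and 0.48.

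Hypoxia and glycolysis genes were mostly higher, with medians of 0.25 and 0.21. Of 17 tested members 11 were higher in both lines and 0 lower in both. The others went opposite ways, with 2 lower in OCM1 and higher in OCM1a and 4 the reverse. NDRG1 had 0.68 and 1.87, the angiogenic factor VEGFA 0.73 and 1.09, the mitophagy receptor BNIP3 0.84 and 0.72, and the glucose transporter SLC2A1 0.45 and 0.70. The glycolytic enzymes PGK1, with 0.21 and 0.00, and LDHA, with 0.07 and -0.03, named after their values were seen, differed little. Stress genes of the integrated stress and unfolded protein responses had medians of 0.22 and 0.24, with 15 of 17 higher in both lines. Set against the OCM1 array without decoy, a control chosen after seeing the data that brings in the difference between the lines, the OCM1a stress median was 0.08, at the 84.6 percentile of random lists, so it depends on the control array. With that control the hypoxia median was 0.19, but VEGFA had 0.35. DDIT4 had 1.48 and 0.52, SESN2 1.15 and 0.14, the asparagine synthetase ASNS 0.37 and 0.64, and HERPUD1 0.63 and 0.28. Camera gave adjusted p values of 8.93e-06 for hypoxia and 1.50e-06 for stress, and for either list an adjusted p of 0.745 with an estimated correlation. Adjusted over the list alone, 4 hypoxia genes and 1 stress gene passed limma, against 0 over all genes.

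Mitotic genes had medians of 0.03 in OCM1 and 0.21 in OCM1a, with MKI67, a marker of cycling cells, at 0.09 and 0.55, CDK1 at 0.05 and 0.49, KIF20A at 0.15 and 0.36 and TOP2A at 0.16 and 0.33. BCL2 family genes had medians of 0.21 and -0.02, with BCL2A1 at 0.16 and 1.15, PMAIP1 at 0.48 and 0.78, HRK at 0.50 and 0.24 and BAX at 0.41 and 0.21. Their OCM1a mean was 0.15, so median and mean differ in sign. Targets of p53 had medians of -0.01 and 0.14, at the 48.0 and 94.0 percentiles of random lists and so within their central 95%, and means of 0.09 and 0.23, with PHLDA3 at 0.10 and 0.76 and GDF15 at -0.09 and 0.83. The mitotic median in OCM1, at the 95.3 percentile, and the BCL2 family median in OCM1a, at the 30.9 percentile, also lay within that range. By their medians none of these lists stood out in both lines. Camera called these 3 lists higher, with adjusted p values of 0.00561, 0.00951 and 0.0332, and each had an adjusted p of 0.821 with an estimated correlation. In limma 0 of their members passed over all genes or adjusted over the list alone.

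**Figure D2:**
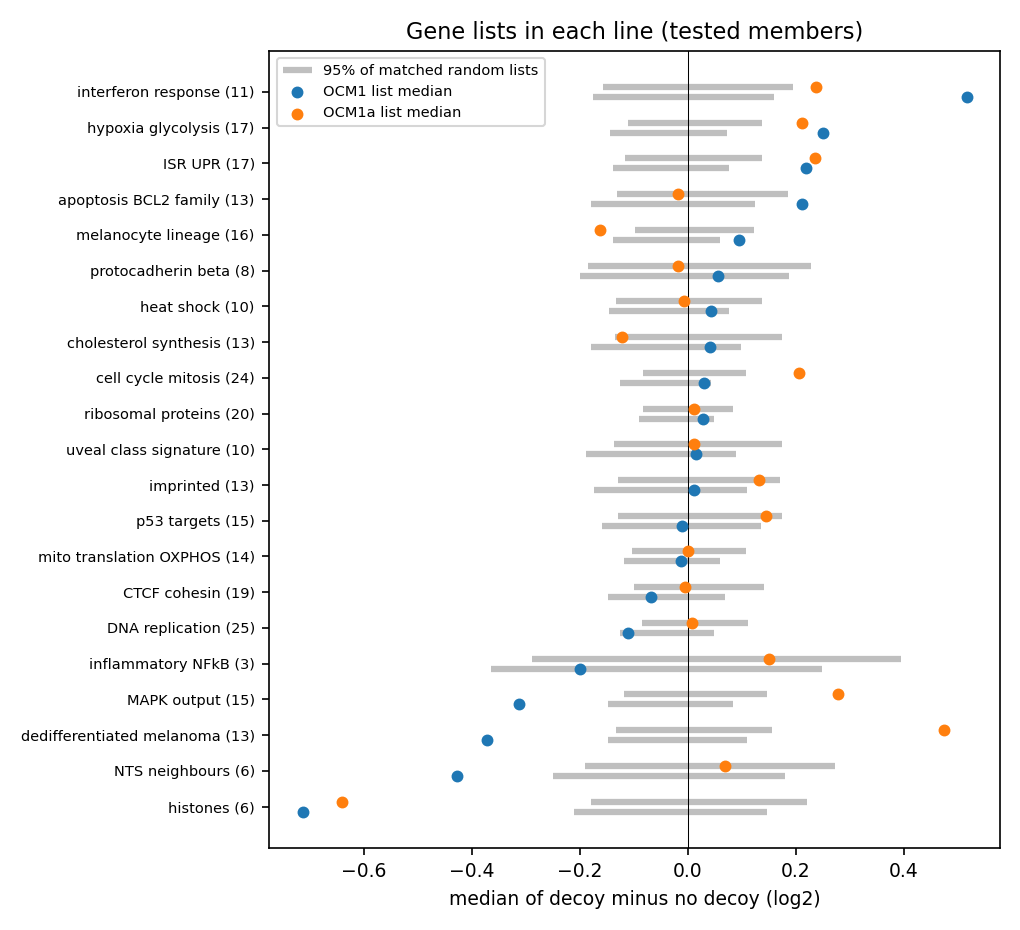
Median log2 difference with decoy of the tested members of each gene list, a blue point for OCM1 and an orange point for OCM1a, with tested members in brackets and grey bars for the central 95% of 10000 matched random lists. Interferon response lies at 0.52 and 0.24, histones at -0.71 and -0.64, and dedifferentiated melanoma at -0.37 and 0.48.

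In OCM1 alone, the lowest genes with decoy were SORBS2, AXL, THBS1, CCN2 and PCDH7. SORBS2, an adaptor at the actin cytoskeleton, the receptor tyrosine kinase AXL and CCN2, the connective tissue growth factor, had signals with decoy of 5.73, 6.10 and 6.34, under the G- and C-rich background of 6.89. Against that background they were at least 3.11-fold, 3.94-fold and 3.40-fold lower, and their order is not known. The matrix protein THBS1 was 4.99-fold and the protocadherin PCDH7 3.28-fold lower. A dim AXL probe set gave only -0.18, and averaged over its probe sets PCDH7 had -0.41. The highest genes were BST2, the antiviral membrane protein tetherin, 5.04-fold, PRDM7 4.13-fold, the lipid carrier APOD 4.07-fold, ISG15 3.58-fold and IFITM1, an antiviral membrane protein, 3.28-fold. In all, 26 genes were at least 2-fold higher and 28 at least 2-fold lower, with no test.

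In OCM1a alone, more genes were higher than lower with decoy. ARMCX1 was 8.09-fold higher, the calcification inhibitor MGP 6.93-fold, the WNT antagonist SFRP1 5.92-fold, the receptor tyrosine kinase MET 4.04-fold and TMEM47 3.81-fold. The lowest genes were STAC3, at least 2.60-fold since its signal of 5.84 with decoy lay under the background of 6.77, PTPRZ1, 4.55-fold, BST2, 3.13-fold, the cold-sensing channel TRPM8, 3.05-fold, and the cytokine IL17D, 2.98-fold. At 2-fold or more, 90 genes were higher and 24 lower, with no test. With the OCM1 array without decoy as the control, a choice made after seeing the data, 57 were higher and 29 lower, and ARMCX1 was 5.14-fold and MGP 3.02-fold higher.

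Differences in OCM1a also followed chromosomes. Of the 332 tested genes on chromosome 10, 89.2% were higher with decoy in OCM1a, with a median of 0.32, against 40.4% and -0.05 in OCM1. Of the 159 on chromosome 13, 21.4% were higher in OCM1a, with a median of -0.28, against 41.5% and -0.06 in OCM1. This covered part of chromosome 13, since over 4 equal parts of its gene order 5%, 5%, 17.5% and 59.0% of genes were higher in OCM1a, and the last part had a median of 0.06. Among 215 blocks of about 40 consecutive tested genes, 17 on 8 chromosomes had a median in OCM1a beyond any of 1000 shuffles of gene order. OCM1 had 2 such blocks, both on chromosome 4, and the arrays without decoy, set against each other, had 0. Leaving out chromosomes 10 and 13 left 79 higher and 21 lower genes in OCM1a. Other chromosomes with shifted parts stayed in, so these counts are not free of such shifts. By the same 4 parts, the last 2 of chromosome 2 had OCM1a medians of -0.23 and -0.18. The first 2 of chromosome 6 had -0.18 and -0.21, and the first of chromosome 18 had -0.22. On chromosome 3 the first part had -0.18 and the last 0.21. Chromosomes were looked at after the values were seen.

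**Figure D3:**
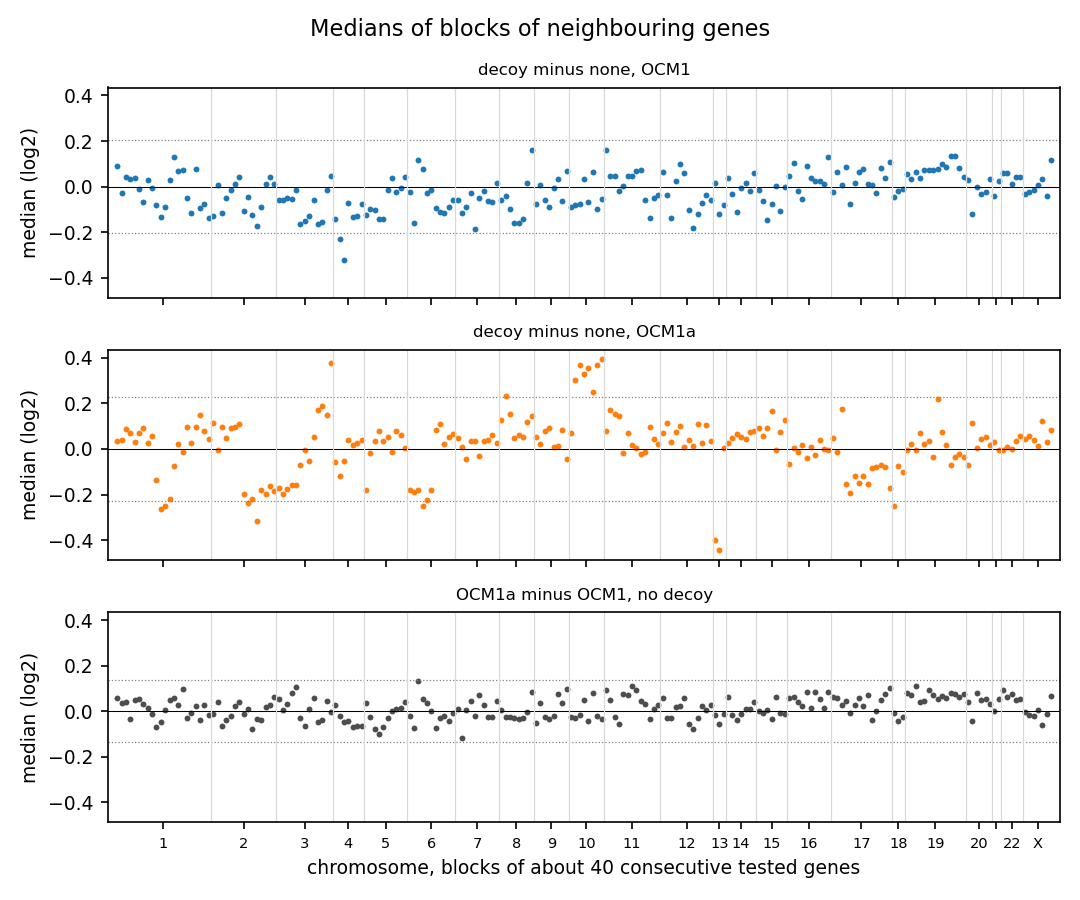
Median log2 difference of each of 215 blocks of about 40 consecutive tested genes along the chromosomes, for decoy minus no decoy in OCM1 and in OCM1a and for OCM1a minus OCM1 without decoy, with dotted lines at the largest absolute median of 1000 shuffles. Blocks reach 0.39 and -0.45 in OCM1a, and stay between -0.12 and 0.13 without decoy.

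The 2 lines were then compared for their response. Of 13 tested genes of dedifferentiated melanoma, 8 were lower with decoy in OCM1 and higher in OCM1a, 3 higher in both, 1 lower in both and 1 the reverse, with no test of the difference. The medians were -0.37, below every random list, and 0.48, above every random list. AXL had a bound of -1.98 and 0.48, THBS1 -2.32 and 1.04, the neurotrophin receptor NGFR -1.68 and 0.44, and ZEB1, a transcription factor of mesenchymal cells, 0.34 and 1.05. With the OCM1 array without decoy as control the OCM1a median was 0.39. Genes of MAPK output, 8 of 15 lower in OCM1 and higher in OCM1a, had medians of -0.31 and 0.28, with cyclin D1 (CCND1) at -0.13 and 1.63, while the feedback genes DUSP6, with -0.58 and -0.40, SPRY4, with -0.34 and -0.24, and SPRY2, with -0.33 and -0.19, were lower in both lines. With that control the MAPK median in OCM1a was 0.12, at the 92.5 percentile, so it depends on the control array. Melanocyte genes, 7 of 16 higher in OCM1 and lower in OCM1a, had medians of 0.09, at the 99.7 percentile, and -0.16, at the 0.21 percentile, while over all 19 measured genes OCM1 had 0.03, at the 86.9 percentile, and OCM1a -0.16, at the 0.335 percentile. The OCM1 side thus depends on the filter. The OCM1a side was smaller against the OCM1 array without decoy, at -0.09 and the 1.54 percentile. In that list were the pigment enzyme TYRP1 at 0.34 and -1.13 and RAB38 at 0.03 and -0.48. Within that list EDNRB, with -0.56 and -0.64, and MLPH, with 0.56 and 0.57, had the same direction in both lines. Camera over both lines gave adjusted p values of 0.738 for the dedifferentiated and MAPK lists and 0.594 for the melanocyte list. Opposite differences cancel in camera and limma over both lines, so these tests do not bear on the contrast between the lines. Adjusted over the list alone 0, 0 and 2 genes passed limma, against 0 over all genes.

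Single genes also parted by line. At least 2-fold lower in OCM1 and 2-fold higher in OCM1a were 8 genes, CCN2, CRIM1, ITIH5, MYOF, NRCAM, NT5E, SORBS2 and THBS1, where independent lists would give 0.278. Counts of genes that went the same way also lay above independence, so the excess is not particular to opposite directions. Against the OCM1 array without decoy, 5 of the 8 stayed 2-fold higher in OCM1a, while SORBS2 had 0.62, ITIH5 0.59 and NT5E 0.66. BST2 went the other way, with 2.33 and -1.65. Those among them outside the rule were chosen after their values were seen. In a signature of YAP and TAZ targets, a set formed after seeing the data, 9 of 12 tested genes were lower in OCM1 and higher in OCM1a. The others were GADD45A with 0.51 and 0.67, LATS2 with 0.19 and -0.11, and ASAP1 with -0.19 and -0.16, and all 22 measured genes had medians of -0.14 and 0.34. CCN2, CRIM1, MYOF and NT5E of the 8 genes above are members, so the set is not separate support. Across the 9054 tested genes, which are not independent replicates, the differences in the lines had a Pearson correlation of -0.03 and a Spearman correlation of -0.04, and 47.0% had the same direction.

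**Figure D4:**
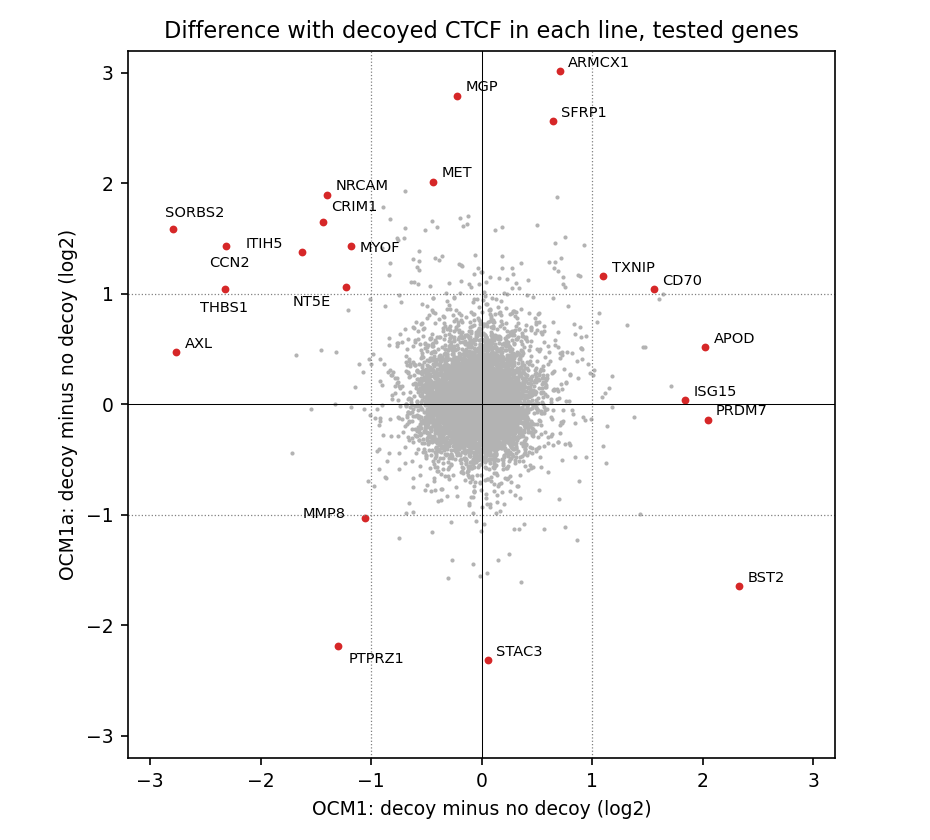
Log2 difference with decoy in OCM1 (horizontal) against OCM1a (vertical), each point one of 9054 tested genes, with named genes in red and dotted lines at 2-fold. CD70 and TXNIP lie beyond 2-fold at the upper right, PTPRZ1 and MMP8 at the lower left, and 8 genes with CCN2 and THBS1 at the upper left.

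The lines themselves were compared across both conditions. The genes that the rule took as highest in OCM1a had a mean log2 difference, OCM1a minus OCM1, of 1.84 for THBS1, 1.57 for CRIM1, 1.30 for the tropomyosin TPM1 and 1.18 for MYOF. With signals raised to the G- and C-rich background, CCN1 had at least 2.07, CCN2 1.79, AXL 1.12 and SORBS2 0.64. Their order is not known. On the side of OCM1 were BST2 with -2.26, the adhesion receptor CXADR with -1.25, PLA1A with -1.23, CRYL1 with -1.17, TMEM255A with -1.07 and APOD with -1.01, and, with signals raised to that background, STAC3 with -1.11 and SCUBE2 with -1.02. For each of these genes the lines lay further apart on the arrays with decoy, where SORBS2, AXL, CCN2 and CCN1 in OCM1 and STAC3 and SCUBE2 in OCM1a were under the G- and C-rich background. CXADR was already at -0.78 without decoy. Without decoy the direction was turned for SORBS2, with -0.97, AXL, with -0.11, MYOF, with -0.13, and SCUBE2, with 0.17. Without decoy, CCN1, with 1.24, and MGP, with -1.20, were the only tested genes at least 2-fold apart between the lines. Between the arrays with decoy 126 genes were higher and 62 lower in OCM1a by that measure. In limma 0 genes passed either way, the smallest adjusted p was 1, and 263 genes had an unadjusted p under 0.05.

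The medians of the remaining lists lay within the central 95% of random lists in both lines. Against the OCM1 array without decoy this did not hold in OCM1a for cholesterol synthesis, with -0.40, and beta protocadherins, with -0.30. Genes of CTCF and cohesin had medians of -0.07 and -0.01, with the cohesin regulators PDS5B at -0.27 and -0.47 and PDS5A at -0.42 and -0.17 and the looping factor LDB1 at 0.12 and 0.43. DNA replication genes had -0.11 and 0.01, with CCNE2 at -0.92 and -0.13 and CCNE1 at 0.08 and 0.63. Cholesterol synthesis genes had 0.04 and -0.12, with HMGCS1 at -0.51 and -0.46 and MSMO1 at -0.23 and -0.41. Ribosomal proteins had 0.03 and 0.01, mitochondrial translation and respiration genes -0.01 and 0.00, and heat shock genes 0.04 and -0.01 with BAG3 at 0.22 and 0.87. Imprinted genes had 0.01 and 0.13, with PEG3 at -0.50 and 0.89 and CDKN1C at 0.07 and 0.82. Beta protocadherins had 0.06 and -0.02 with PCDHB13 at 0.07 and -0.90, and genes of the uveal melanoma class signature 0.01 and 0.01 with ID2 at -0.93 and -0.40 and ECM1 at 0.34 and 0.68. The 3 tested inflammatory genes had a median of -0.20 and 0.15, with ICAM1 at 0.03 and 0.37. Means and medians differed in sign for imprinted genes, with a mean of -0.07, and the uveal signature, with -0.04, in OCM1, and for heat shock genes, with 0.07, beta protocadherins, with 0.03, and mitochondrial genes, both near 0, in OCM1a. Camera gave these 10 lists adjusted p values from 0.380 to 0.879, and 0 of their genes passed limma over all genes or adjusted over the list alone.

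Markers of other cell types were mostly under the filter. Above it were 0 of 8 endothelial, 1 of 10 fibroblast, 2 of 11 immune, 2 of 12 epithelial and 1 of 6 retinal pigment epithelium genes. The fibroblast gene was LUM, a matrix proteoglycan, with -0.65 and -0.89. The epithelial genes were KRT18, with 0.28 and -0.21, and SFN, with 0.32 and 0.00, the immune genes FCER1G, with 0.46 and 0.00, and TYROBP, with 0.22 and -0.15, and the pigment epithelium gene RLBP1, with 0.30 and -0.23.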

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

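The test of the opposite genes against shifts of neighbouring genes was set before its result was seen, and the other tests here, with the YAP gene set, the swap of the control array and the floor at background, were chosen after it. Genes and list medians are given because they went opposite ways in OCM1 and OCM1a with decoyed CTCF, and this difference between the lines was not tested, since each line has 1 array per condition.

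The log2 difference with decoy in OCM1a minus that in OCM1 was 3.74 for CCN2, 3.09 for CRIM1, 3.00 for ITIH5, 2.61 for MYOF, 3.30 for NRCAM, 2.28 for NT5E, 4.38 for SORBS2 and 3.36 for THBS1, all lower in OCM1 and higher in OCM1a. SORBS2 and CCN2 were under the G- and C-rich background with decoy in OCM1, and with signals raised to it their OCM1 differences were -1.64 and -1.76. For BST2 the difference in OCM1a minus that in OCM1 was -3.98, higher in OCM1 and lower in OCM1a. Among the lists, the median in OCM1a minus that in OCM1 was 0.59 for MAPK output, 0.85 for dedifferentiated melanoma and -0.26 for melanocyte genes. Against the OCM1 array without decoy the OCM1a medians were 0.12 for MAPK output, 0.39 for dedifferentiated melanoma and -0.09 for melanocyte genes, so the first and last are smaller with that control. Over all 19 measured melanocyte genes the OCM1 median lay at the 86.9 percentile, so the OCM1 side of that contrast depends on the filter.

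CCN2, CCN1, AXL, CRIM1, MYOF and NT5E belong to a signature of 22 targets of YAP and TAZ, coactivators that respond to cell density and adhesion. Its 12 tested genes had medians of -0.78 and 0.58, against -0.14 and 0.34 over all measured genes. The set was formed after these genes were seen, so its medians in part restate that choice. Its other genes lower in OCM1 and higher in OCM1a were FJX1 with -0.29 and 0.21, DOCK5 with -0.38 and 0.44 and FOXF2 with -0.06 and 1.18. GADD45A, LATS2 and ASAP1 did not go that way. AXL, CCN1 and CCN2 are also in the dedifferentiated melanoma list, so these lists are not independent. The OCM1a array without decoy does not account for the contrast, since against the OCM1 array without decoy the OCM1a median was 0.62. Subtracting the median of each block of 40 neighbouring genes left 0.72 in OCM1a. No block median there rose above 0.39, under the list median of 0.58, so that test could hardly have given a value near 0. Shifts of whole blocks are thus too small to account for that median, and shorter segments were not tested. Normalization between arrays stays open, since quantile normalization, which left medians of -0.74 and 0.52, moved genes of these already normalized arrays by a median of only 0.05 in OCM1 and 0.06 in OCM1a. Variation between cultures, such as density at harvest, stays open and cannot be told apart from a line-specific response to the decoy, because there was 1 culture per line and condition. The SD of the line difference over the list without decoy was 0.28 of that with decoy, which may reflect similar cultures without decoy but does not exclude it.

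Control transcripts that no comparison uses also stood out. Poly-A spike-ins were higher by a median of 0.56 with decoy in OCM1a than without. The 18S rRNA probe sets were higher by 1.13 with decoy in OCM1a than without.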

How the results depend on the processing

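The swap of the control array, the adjustments for chromosomes, the floor at background and, for lists, the upper 25% by signal and centring were added after seeing the data. With the intensity trend in limma, the decoy effect over both lines had 12 genes higher and 3 lower, against 0 and 0, while robust eBayes, adjusted p under 0.10, both normalizations, both filters, the mean over probe sets and the fit with no replicate block for the line gave 0 either way. Counts are given below as higher in OCM1, lower in OCM1, higher in OCM1a, lower in OCM1a, higher in both, lower in both, lower in OCM1 but higher in OCM1a, and the reverse. They were 131, 178, 352, 129, 32, 14, 34 and 7 at 1.5-fold and 3, 4, 4, 2, 0, 0, 0 and 0 at 4-fold, which follows from the threshold. With no filter on dim genes they were 54, 63, 194, 44, 9, 3, 20 and 3, and with only the upper 25% by signal 5, 6, 21, 9, 0, 0, 3 and 0, where more or fewer genes enter. Quantile normalization gave 1 gene higher in both lines and 2 of the reverse kind, centring gave 2 of the reverse kind, and the mean over all probe sets gave 1 lower in both and 5 lower in OCM1 but higher in OCM1a. The cause was not tested. With the OCM1 array without decoy as control, 57 genes were higher in OCM1a and 6 lower in OCM1 but higher in OCM1a, the OCM1a median of MAPK output was 0.12 and that of stress genes 0.08, and subtracting the median of 40 neighbouring genes left 1 lower in both lines and 2 of the reverse kind. With an estimated correlation camera called 0 lists against 7. With only the upper 25% by signal it called 4, since histones, with 3 genes left, had an adjusted p of 0.0845 and the interferon and p53 lists had under 3 genes left and so no test. The NTS neighbour list had an adjusted p of 0.0476 after quantile normalization, on the same 6 genes without NTS, and 0.000781 with no filter, on 12 genes with NTS, against 0.0689, and without the filter the NTS signalling list of 3 genes, not tested otherwise, also had 0.000781. Averaging probe sets moved NTS in OCM1 to -1.03. No 2-fold difference of a named gene and no list call turned its direction under the alternatives run. Across the alternatives run, 81 counts of genes or lists stayed within 1.5 times, 39 moved by more, 2 of genes rose from 0 and 2 of lists dropped, and for single values 1399 stayed within the spread used and on their side of the threshold, 36 moved by more and 15 passed under the trend. Leaving out a line leaves 1 array per condition, so a value with no test. The planned offsets were not run because the table was already on a log scale. Signal over background limits NTS and other genes under the filter, and also 7 tested genes that were under the G- and C-rich background on an array, among them SORBS2, AXL, CCN2, CCN1, STAC3 and SCUBE2. Raising all signals to that background left each count at 2-fold as it was.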

Other observations

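Of the tests below, that of chromosome copies was chosen after the results were seen, and those of normalization, probe set noise and adjacent genes were set before. With an intensity trend in the limma variance model, 15 genes passed for the decoy over both lines, and those not described so far were named after their values were seen. Among them were the neurofilament NEFL at 1.64 in OCM1 and 0.997 in OCM1a, the actin-capping CAPG at 0.75 and 1.51, the tubulin TUBA1A at 0.95 and 0.62, and CDC42EP3 at 0.89 and 1.16. The costimulatory receptor CD40 had 0.87 and 1.17, the antiviral IFITM3 1.06 and 0.83, the small heat shock protein HSPB8 0.72 and 1.32, GPRIN3 0.92 and 1.45 and the nuclear RNA MALAT1 0.75 and 1.06. With the OCM1 array without decoy as control, TUBA1A had 0.08 and MALAT1 0.11 in OCM1a, so both depend on the control array. The others just named had 0.71 or more. Adjusted p values of the 15 genes in that model ran upward from 0.0281 for PTPRZ1, and without the trend the smallest over all genes was 0.261.

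After quantile normalization the OCM1 median of the interferon genes was 0.56, but that step moved genes little on arrays already normalized, so normalization stays open for their higher levels. Since what the cells without decoy received is not given, an effect of decoyed CTCF and a response to its delivery stay open as well.

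The differences between single arrays are larger than probe set noise would give, since differences of 2 probe sets of a gene correlated across 364 genes at 0.69 in OCM1, 0.76 in OCM1a and 0.35 between the lines without decoy. Adjacent genes had rank correlations of 0.17 in OCM1 and 0.25 in OCM1a, beyond 10000 shuffles, but also 0.15 between the lines without decoy, so this is not particular to the decoy. Genes 50 places apart still correlated at 0.18 in OCM1a, against 0.04 in OCM1. Together with 89.2% of chromosome 10 genes and 21.4% of chromosome 13 genes higher in OCM1a, the latter shift covering part of the chromosome, this is consistent with other copy numbers of chromosomes or parts of them in the OCM1a cells with decoy than in those without, a hypothesis that a genomic measurement could test. Of such shifts, the decoy as their source and an outgrowth of other cells in that culture both stay open.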
